A study of Mus musculus with 6 samples.

How the data were processed

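Whole brains of mouse embryos at embryonic day 16.5 were dissected, frozen and homogenized, per the labels' protocols. Total RNA was extracted with Trizol, purified on columns, labelled with Affymetrix whole-transcript reagents and read on Affymetrix Mouse Gene 1.0 ST arrays, 1 per brain. The genotype and replicate number of each array came from the sample titles, which call the 3 samples of each genotype biological replicates.

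The deposited values were on a log2 scale. The authors normalized them with Robust Multi-Array Average (RMA), per the series text, and the submitters' processing notes name Affymetrix Expression Console without a version. RMA gives log2 values, and the deposited table states no log base. In the deposited table the median of every row over the 6 arrays was 0 to within 5e-07, a centring that neither the labels nor the table describe. Centring keeps differences between arrays and removes each gene's level, so no filter on low values and no variance trend with intensity could be applied. The level of probe summary and the genome build of the array annotation are not given in the sources used here. The series text sets a 1.5-fold limit and a corrected p limit of 0.05 and names no test.

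Rows were named through the platform annotation. Of 28856 rows, 21789 named 1 gene, 1621 named several and 5446 named none (18.9%). Rows naming at least 1 gene (23410) were tested, and genes were named only from rows with 1 gene. Symbols were updated by gene identifier through a RefSeq gene table of assembly GRCm38.p6, which held 21766 of the single-gene rows. That table was used for names, chromosome, neighbour order and class of genomic span (known for 99.9% of genes), and no coordinates are printed because the array's build is not named. Of 19938 genes, 999 had several rows, and in none of these was 1 row called higher and another lower. Gene lists and spans used 1 row per gene, the single-gene row with most accessions. The rule fixed beforehand, the row with the highest mean, could not be used because levels are centred away.

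Genotypes were compared with limma 3.58.1 in R 4.3.3, with lmFit and the eBayes moderated test, two-sided, and Benjamini-Hochberg adjustment over 23410 rows. Errors of differences are limma's moderated standard errors. A row was called at an adjusted p under 0.05, and at 1.5-fold where the fold was also at least 1.5. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, two-sided, with adjustment over 44 lists of at least 5 measured genes. The lists covered DNA repair, stress responses, metabolism, neural cell types, other cell types the dissection could hold, sex-linked genes and neighbours of Tdp2. Of 926 list genes, 838 distinct genes were matched, and genes with no single-gene row, such as Cdkn1a, were not analysed here. Genes over 100 kb were tested as 1 further set. Figures were drawn with matplotlib 3.10.9.

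The genes named were Tdp2, the 15 largest rises and 15 largest falls among called genes whose groups did not overlap, the called members of each list and up to 4 members of smallest p. Top2a, Top2b, Tdp1, Mdm2, Acot13, Gmnn, Xist, Ttr and Hbb-y were always named. The rule, the lists, the tests and most alternatives were set before the data were examined.

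The steps were tested on simulated data for the comparison of the mutant with the wild type, 3 arrays each, in 10 rounds over 23410 rows with 200 changed. Calls in the simulation were scored at an adjusted p under 0.05 without the fold limit. The fit recovered 99.9% of rows changed 1.5-fold and 100% of those changed 2-fold, and 3.14% of its calls were false. The call that also requires a 1.5-fold change was not scored. A list of 25 genes shifted by 0.1 passed in 10 of 10 rounds and an unshifted list in 0 of 10. Those rows were simulated as independent, so the list result does not cover correlated genes. Noise was normal, with row SDs shrunk toward their geometric mean. The recovered and false shares therefore do not describe noisier rows or arrays that vary together.

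Alternatives were the replicate number as a block, each array left out, all rows, array medians set equal, cyclic loess (which here acted on centred values), array weights, rows outside X and Y, a plain two-sided t-test, a 2-fold limit, limma's treat against 1.2-fold and an unadjusted p. For lists they were camera with estimated correlations, fry and camera on ranks, and for long genes a limit of 200 kb. A robust variance prior and the single row per gene were added after the data were seen.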

Results

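RNA from the whole brain of mouse embryos at embryonic day 16.5 was measured on 6 arrays. The brains covered the olfactory bulb, forebrain, midbrain, hindbrain and brain stem. Of the embryos, 3 were wild type and 3 were Tdp2Δ1-3, a deletion of exons 1 to 3 of Tdp2. Tdp2 encodes the tyrosyl-DNA phosphodiesterase that removes trapped topoisomerase II peptide from 5' ends of DNA breaks. The comparison of the 2 genotypes asks which transcripts differ in the embryonic brain when this enzyme is lost. Each of the 28856 values per array was a log2 value centred on its median over the 6 arrays, so levels between genes cannot be compared. Array medians lay between -0.011 and 0.014. The number of arrays, 3 per genotype, limits the precision of every difference.

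Tdp2 was lower in every mutant brain than in every wild-type brain. Its centred log2 values were 0.90, 1.10 and 1.34 in the wild types and -1.05, -0.90 and -0.94 in the mutants. The difference, mutant minus wild type, was -2.07 ± 0.10 (SE, n = 3 per genotype), 4.21-fold lower (limma adjusted p = 0.00035). The array row may include probes outside the deleted exons, which would not test the deletion. Acot13, a thioesterase gene that lies next to Tdp2 on chromosome 13, fell by 1.26 ± 0.07 (SE), 2.40-fold (limma adjusted p = 0.00081). Among 20 fixed neighbours of Tdp2, Acot13, Carmil1 and Nrsn1 fell and Gmnn rose by 0.19 (limma adjusted p = 0.037), while 16 did not pass. Nrsn1 ranged from -0.56 to -0.06 across all alternatives, and Acot13 from -1.32 to -1.21. Adjusted over the list alone, 2 neighbours rose and 6 fell. The neighbour list had a median of -0.0033 and was not shifted as a set (camera adjusted p = 0.28). That list also held genes such as Sox4, E2f3 and Id4, which lie more than 20 protein-coding genes from Tdp2, so the set result does not describe close neighbours alone. Without mutant replicate 1, 2 neighbours rose and 5 fell. No neighbour rose with any other array left out, and only 1 fell without wild-type replicate 2 or mutant replicate 2 or 3.

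**Figure D1:**
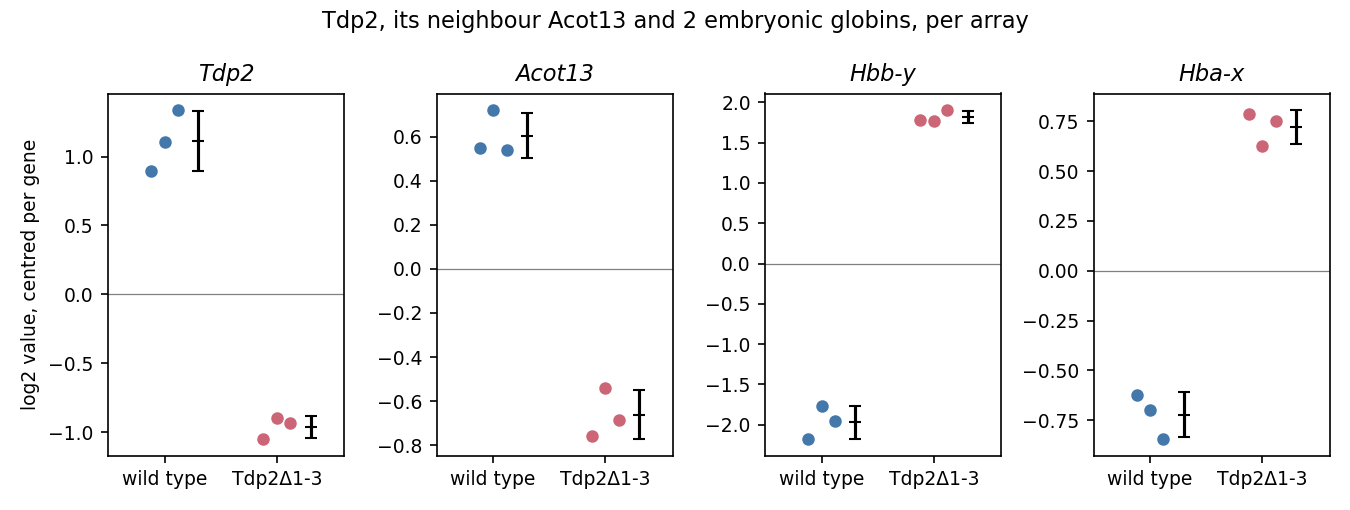
Centred log2 values of Tdp2, Acot13, Hbb-y and Hba-x in each of the 6 arrays (coloured points), with the mean and SD of the 3 arrays of each genotype (black bars); each panel has its own vertical axis. Tdp2 and Acot13 lay lower in all 3 mutants, and Hbb-y lay between -2.18 and -1.77 in the wild types and between 1.77 and 1.91 in the mutants.

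The largest rises were in the embryonic globins Hbb-y and Hba-x. Hbb-y, an embryonic beta-like globin, rose by 3.79 ± 0.10 (SE, n = 3 per genotype), 13.8-fold (limma adjusted p = 5.4e-06). Hba-x, the embryonic alpha-like globin on chromosome 11, rose by 1.44 ± 0.07, 2.72-fold (limma adjusted p = 0.00035). The other 13 red-cell genes measured did not pass. Among them were Hbb-bh1, also an embryonic beta-like globin, at 0.14 (adjusted p = 0.13) and Car2 at -0.13 (adjusted p = 0.36). The rise was therefore not shared by all embryonic globins measured. The red-cell list had a median of 0.04 (camera adjusted p = 0.047, but adjusted p = 0.38 with an estimated correlation), and 2 genes rose adjusted over the list alone. That call was lost without wild-type replicate 1 (adjusted p = 0.069), wild-type replicate 3 (0.058) or mutant replicate 1 (0.20). The rises of Hbb-y and Hba-x passed with any 1 array left out, with adjusted p at most 0.00035 and 0.0058.

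The other 13 of the 15 largest rises were smaller. Nhlh1 rose by 0.90, Tal2 by 0.75, the proneural factor Neurog2 by 0.75 and the homeobox gene Dbx1 by 0.73. The spindle checkpoint kinases Bub1 and Bub1b rose by 0.78 and 0.70, and the kinetochore gene Knl1 rose by 0.75. The mitotic kinesins Kif11 and Kif2c rose by 0.74 and 0.70, the condensin subunit Ncapg by 0.78 and Top2a, topoisomerase II alpha, by 0.72. Hmgb2 and Cks2 rose by 0.71 and 0.70. The SEs of these 13 genes lay between 0.06 and 0.13. After Tdp2 and Acot13, the largest falls were in Ptgds (-1.19), which encodes a prostaglandin D synthase, the GABA transporter gene Slc6a11 (-1.09) and Mal2 (-1.07). The size of the fall of Mal2 depended on the processing. Mal2 ranged from -1.25 to -0.49 across all alternatives, and Slc6a11 from -1.32 to -0.79. The metabotropic glutamate receptor gene Grm3 fell by 0.96, Thy1 by 0.91, the kainate receptor partner Neto1 by 0.88 and Cntn1 by 0.82. Necab1 fell by 0.96, Caln1 by 0.87 and Vsnl1 by 0.85. Dgkk fell by 0.91, Stum by 0.86 and Plppr5 by 0.85.

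At a fold of 1.5 and a limma adjusted p under 0.05, 150 of 23410 gene rows changed, 44 higher and 106 lower in the mutants (70.7% lower), and they stood for 143 distinct genes. After cyclic loess normalization of the centred values the split was 57 higher and 82 lower (59.0% lower). In 25.7% of all rows the groups did not overlap, against 10% by chance. Without the fold limit 1515 rows changed, 548 higher and 967 lower, and with array weights 2644 were higher and 2781 lower. With the replicate number as a block 904 were higher and 1496 lower. The counts depended on which array was left out. The 153 called genes of the gene lists all kept their sign in these fits, but they were called on the same arrays. Where groups do not overlap, leaving out 1 array cannot turn a sign, so the kept signs add no support. The 1.5-fold count was 89 without wild-type replicate 1, 211 without wild-type replicate 3, 282 without mutant replicate 1, 60 without mutant replicate 2 and 97 without mutant replicate 3. The higher rows among them numbered 23 without wild-type replicate 1, 78 without wild-type replicate 3, 84 without mutant replicate 1 and 10 without mutant replicate 2. The count at any fold was 725 without wild-type replicate 1, 335 without wild-type replicate 2, 2501 without mutant replicate 1, 145 without mutant replicate 2 and 596 without mutant replicate 3. Of the 15 largest rises 7 passed with any 1 array left out, namely Hbb-y, Hba-x, Nhlh1, Neurog2, Kif11, Dbx1 and Kif2c. Of the 15 largest falls 10 did so, among them Tdp2, Acot13, Ptgds, Neto1 and Cntn1. Without wild-type replicate 2, 10 of the rises and 12 of the falls passed, and without mutant replicate 2, 7 and 10. Ncapg also lost its call without mutant replicate 3, and Slc6a11 without wild-type replicate 1.

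Genes of cycling cells rose almost without exception. Of 29 measured, 28 rose and the remaining gene had a positive value that did not pass, with a median log2 fold change of 0.56 over the list. Ccna2, a cyclin of S and G2 phase, rose by 0.59, Mki67, the Ki-67 antigen gene, by 0.56 and the kinetochore gene Cenpf by 0.56. All 29 rose when adjusted over the list alone. The list was shifted up by camera with a preset correlation of 0.01 (adjusted p = 1e-28), but not with an estimated correlation (adjusted p = 0.38). Without mutant replicate 2, 2 members rose, while the median was 0.52. Genes of intermediate progenitors, the dividing neuron precursors of the embryonic forebrain, moved the same way. Of 13 measured, 7 rose, including Gadd45g by 0.63, Neurog2 by 0.75, Btg2 by 0.51 and Mfap4 by 0.28, with a median of 0.25 (camera adjusted p = 5.8e-06, and adjusted p = 0.38 with an estimated correlation). Of these 10 rose and 1 fell when adjusted over the list alone. Without wild-type replicate 1, wild-type replicate 2 or mutant replicate 2, 4, 3 and 2 members rose. Of 15 forebrain transcription factors, Otx1, Nkx2-1, Lhx2 and Fezf2 rose by 0.28, 0.25, 0.35 and 0.37, with a median of 0.16 (camera adjusted p = 0.00031, and adjusted p = 0.38 with an estimated correlation). Of the forebrain factors 7 rose when adjusted over the list alone. None of them rose without wild-type replicate 1 or 2, or without mutant replicate 2 or 3. Of 19 radial glia genes, Nes, Gli3 and Vim rose by 0.49, 0.60 and 0.20 and Tnc fell by 0.44. That list was not shifted (median 0.11, camera adjusted p = 0.18), and adjusted over the list alone 6 rose and 3 fell. None of the radial glia genes passed without wild-type replicate 2 or mutant replicate 2, and the median was 0.05 without mutant replicate 1 or 2.

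Genes of synapses and mature neurons fell. Of 33 measured, 19 fell and the other 14 did not pass, with a median of -0.39. Camk2b, a calcium/calmodulin kinase subunit, fell by 0.57, Nrgn by 0.68, the AMPA receptor gene Gria1 by 0.39 and the synaptic vesicle gene Sv2b by 0.63. When adjusted over the list alone, 29 fell. The shift had a camera adjusted p of 6.2e-20, and an adjusted p = 0.24 with an estimated correlation. Without wild-type replicate 1 or 2, 10 and 6 members fell, and without mutant replicate 2 or 3, 2 and 11 fell. Of 49 long neuronal genes, 21 fell, with Opcml at -0.63, Dlg2 at -0.57, Lingo2 at -0.42 and Negr1 at -0.28. Dcc, Nfia and Sox5 rose. The median was -0.22 (camera adjusted p = 2.4e-12, and adjusted p = 0.38 with an estimated correlation), and adjusted over the list alone 28 fell and 3 rose. Without wild-type replicate 1 or 2 or mutant replicate 2, 11, 4 and 4 fell, and no long neuronal gene rose with any array but mutant replicate 1 left out. Of 16 striatal genes, 6 fell, among them Rxrg by 0.78, Tac1 by 0.39 and the dopamine receptor gene Drd2 by 0.32 (median -0.12, camera adjusted p = 0.0017, and adjusted p = 0.38 with an estimated correlation). Of the striatal genes 6 fell and 1 rose when adjusted over the list alone. Without wild-type replicate 2 or 3 or mutant replicate 3, 3 of them fell, and without mutant replicate 2, 1 fell. Of 36 axon guidance genes, Gap43, Chl1, Sema3a and Sema3c fell and Dcc rose (median -0.10, camera adjusted p = 0.0017, and adjusted p = 0.38 with an estimated correlation). Of these 7 fell and 2 rose when adjusted over the list alone, and no axon guidance gene passed with any array but mutant replicate 1 left out.

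**Figure D2:**
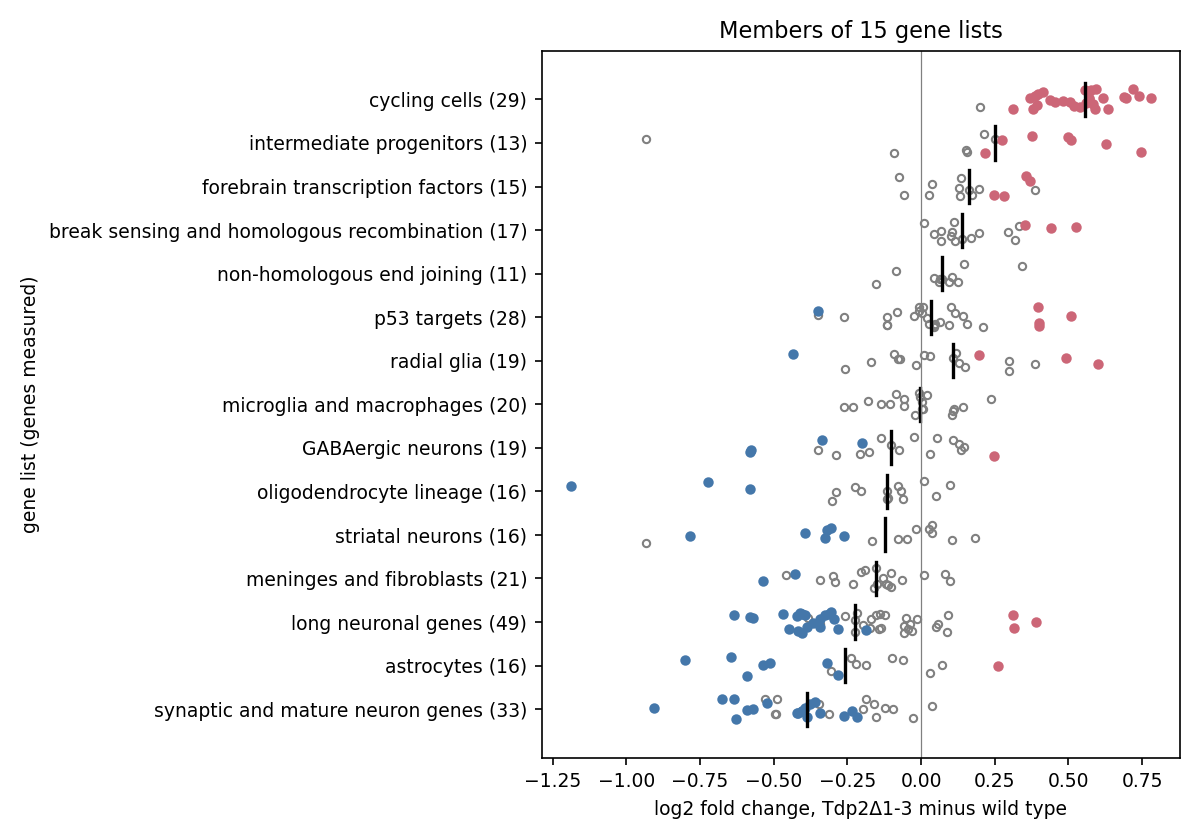
Log2 fold change (mutant minus wild type) of each measured member of 15 gene lists, 1 point per gene, with the list's median as a black bar; filled points passed a limma adjusted p of 0.05 (red higher, blue lower) and open points did not, and the vertical scatter within a list carries no value. Cycling-cell genes lay to the right of 0 with a median of 0.56, and synaptic genes lay mostly to the left with a median of -0.39.

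The GABAergic, glutamatergic, thalamic and hypothalamic lists held changes in both directions. Of 19 GABAergic neuron genes, Calb2, Npy, Calb1 and Gad1 fell by 0.58, 0.58, 0.34 and 0.20 and Nkx2-1 rose by 0.25. Their median was -0.10 (camera adjusted p = 0.030, and adjusted p = 0.38 with an estimated correlation), a call lost without wild-type replicate 3 (adjusted p = 0.067) or mutant replicate 2 (0.059). It was also lost with cyclic loess (0.058), array weights (0.082) and camera on ranks (0.16). Of 21 glutamatergic cortical neuron genes, Crym, Foxp1, Mef2c, Rorb and Sla fell and Fezf2 and Sox5 rose. That list was not shifted with all arrays (median -0.05, camera adjusted p = 0.076), and passed without wild-type replicate 1 (adjusted p = 0.026) or mutant replicate 3 (0.031) and with all array rows (0.023). Adjusted over the list alone, 7 GABAergic genes fell and 1 rose, and 8 glutamatergic genes fell and 3 rose. Without wild-type replicate 2 or mutant replicate 2, 2 GABAergic genes fell, and 2 and then 0 glutamatergic genes fell. No gene of either list rose with any array but mutant replicate 1 left out. The thalamic list (15 genes, median -0.0080, camera adjusted p = 0.39) held 3 falls, Calb2, Cdh6 and Nrgn, and 2 rises, Lhx2 and Lhx9. The hypothalamic list (22 genes, median 0.03, camera adjusted p = 0.67) held falls of Gal and Npy and rises of Nkx2-1 and Sim1. Without mutant replicate 2, 1 thalamic gene fell and none rose, and no hypothalamic gene passed. No thalamic gene rose without wild-type replicate 2 or mutant replicate 3, and no hypothalamic gene rose without wild-type replicate 2. Calb1 fell in the cerebellar list (23 genes, median 0.05, camera adjusted p = 0.86) and Slc6a3, the dopamine transporter gene, in the monoaminergic and cholinergic list (19 genes, median -0.02, camera adjusted p = 0.71). Hoxa7 rose by 0.19 among 23 Hox genes of hindbrain and spinal cord (median 0.03, camera adjusted p = 0.53). The Hox median was -0.04 without wild-type replicate 3 or mutant replicate 1. Gad1, Hoxa7 and Slc6a3 lost their calls with any 1 array left out, and Calb1 without wild-type replicate 2. In peripheral neuron genes (14 measured, median -0.09) Ntrk2 fell by 0.49, and the list was not shifted with all arrays (camera adjusted p = 0.28) but passed without wild-type replicate 3 (0.019). Ntrk2 lost its call without mutant replicate 2. Adjusted over the list alone, 4 thalamic genes fell and 2 rose, 2 hypothalamic genes fell and 2 rose, and 1 cerebellar gene fell. The same count was 2 each way for monoaminergic and cholinergic genes, 0 for Hox genes (1 at an unadjusted p under 0.05 by limma), and 3 falls and 1 rise for peripheral neuron genes.

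The astrocyte, oligodendrocyte lineage and meningeal lists were shifted down by camera with the preset correlation. Of 16 astrocyte genes, 7 fell, including the bicarbonate transporter gene Slc4a4 by 0.80, the water channel gene Aqp4 by 0.51, Sparcl1 by 0.65 and Bcan by 0.59, and Fgfr3 rose by 0.26. The median was -0.26 (camera adjusted p = 5e-05, and adjusted p = 0.47 with an estimated correlation), and adjusted over the list alone 10 fell and 1 rose. Without wild-type replicate 1 or mutant replicate 3 only 1 astrocyte gene fell, and without wild-type replicate 2 or mutant replicate 2 none did. Fgfr3 passed only without wild-type replicate 1. In the oligodendrocyte lineage list Ptgds, Pdgfra and Olig1 fell by 1.19, 0.58 and 0.72 (3 of 16). The list's median was -0.12 (camera adjusted p = 0.00050, and adjusted p = 0.50 with an estimated correlation). When adjusted over the list alone, 4 fell, and without wild-type replicate 2 or mutant replicate 2 only Ptgds did. The oligodendrocyte median was -0.07 without wild-type replicate 1. Across all alternatives Olig1 ranged from -0.92 to -0.06 and Ptgds from -1.31 to -0.93. Whether the fall of Ptgds came from cells of that lineage was not tested. Of 21 meningeal and fibroblast genes, Ogn and the GABA transporter gene Slc6a13 fell by 0.54 and 0.43 (median -0.15, camera adjusted p = 0.00013, and adjusted p = 0.48 with an estimated correlation), and 3 fell adjusted over the list alone. Without mutant replicate 2 no meningeal gene passed, without mutant replicate 1, 5 fell, and with any other array left out 1 fell. The meningeal median was -0.10 without wild-type replicate 1. Across all alternatives Slc6a13 ranged from -0.54 to -0.20 and Ogn from -0.60 to -0.48. Cldn5 and Anpep fell by 0.35 and 0.40 among 23 endothelial and pericyte genes (median -0.04, camera adjusted p = 0.035, and adjusted p = 0.47 with an estimated correlation), with 2 falls adjusted over the list alone. Neither passed without wild-type replicate 1 or 2, or mutant replicate 2 or 3. The endothelial call was lost without wild-type replicate 2 (adjusted p = 0.082) or mutant replicate 3 (0.083). Trpm3 fell by 0.31 among 20 choroid plexus genes, a list not shifted with all arrays (median -0.09, camera adjusted p = 0.073). It passed without wild-type replicate 1 (adjusted p = 0.028) or mutant replicate 1 (0.00056), with all array rows (0.023), with array weights (0.0011) and with camera on ranks (0.029). Trpm3 lost its own call without wild-type replicate 1 or 2 or mutant replicate 2. Ttr, the transthyretin gene, had a value of -0.17 (limma adjusted p = 0.40).

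Loss of an enzyme that acts on topoisomerase II breaks raises the question of repair and damage-response transcripts. Of 17 genes of break sensing and homologous recombination, Chek1, Chek2 and Exo1 rose by 0.53, 0.35 and 0.44, and all 17 had positive values (median 0.14, camera adjusted p = 6.3e-06, and adjusted p = 0.38 with an estimated correlation). When adjusted over the list alone, 8 rose. Chek1 and Exo1 transcripts are more abundant in S and G2 phase of dividing cells, and cycling-cell genes rose in the same arrays (28 of 29, median 0.56). Of the 17 break sensing and recombination genes, 7 rose without mutant replicate 1, 1 without mutant replicate 2, and 2 with any other array left out. Their median was 0.21 without mutant replicate 1. Of 28 p53 targets, Gtse1, Psrc1, Trp53inp1 and Btg2 rose by 0.40, 0.40, 0.40 and 0.51 and Perp fell by 0.35. Gtse1 and Psrc1 encode microtubule-associated proteins of dividing cells, and Btg2 also stood in the intermediate progenitor list. The p53 target list was not shifted (median 0.03, camera adjusted p = 0.15), with 4 rises and 3 falls adjusted over the list alone, and Mdm2 had a value of 0.12 (limma adjusted p = 0.17). Without mutant replicate 2, 2 p53 targets rose. None of 11 non-homologous end joining genes passed limma's adjusted p, and 4 had an unadjusted p under 0.05, with Xrcc5 at 0.34 (adjusted p = 0.064). That list had a median of 0.07 (camera adjusted p = 0.13), and passed only without wild-type replicate 2 (adjusted p = 0.049). Among 7 topoisomerase genes Top2a, also a member of the cycling-cell list, rose, Top1 had a value of 0.37 (adjusted p = 0.052), Top2b of 0.13 (adjusted p = 0.30) and Tdp1 of 0.12 (adjusted p = 0.28). The topoisomerase list had a median of 0.12 (camera adjusted p = 0.037, and adjusted p = 0.47 with an estimated correlation), with 2 rises adjusted over the list alone. Its call was lost without wild-type replicate 1 (adjusted p = 0.066), wild-type replicate 2 (0.055), mutant replicate 2 (0.059) or mutant replicate 3 (0.077), and its median was 0.07 without mutant replicate 2. Casp6 rose by 0.33 among 15 apoptosis effectors (median 0.02, camera adjusted p = 0.47), with 4 rises adjusted over the list alone. No apoptosis gene rose without wild-type replicate 2 or mutant replicate 2 or 3, and 2 rose without wild-type replicate 1 or 3.

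Stress and metabolic lists held few changed genes. Npas4 fell by 0.29 among 21 immediate early genes (median -0.06, camera adjusted p = 0.030, and adjusted p = 0.53 with an estimated correlation), and Ifit3 fell by 0.25 among 22 interferon response genes (median -0.05, camera adjusted p = 0.030, and adjusted p = 0.55 with an estimated correlation). The first call was lost without wild-type replicate 1 (adjusted p = 0.082) or mutant replicate 3 (0.13), and the second without wild-type replicate 1 (0.12) or mutant replicate 1 (0.16). The immediate early median was -0.02 without mutant replicate 3, and the interferon median -0.02 without wild-type replicate 1. Ndrg1, Bnip3 and Vegfa fell by 0.34, 0.29 and 0.22 among 19 hypoxia genes, a list not shifted with all arrays (median -0.05, camera adjusted p = 0.076). It passed without wild-type replicate 1 (adjusted p = 0.046) or mutant replicate 2 (0.049), with all array rows (0.023) and by fry (0.025). Of the hypoxia genes 1 fell without wild-type replicate 2 and none without mutant replicate 2. Arntl and Cry2 fell by 0.22 and 0.23 among 14 core clock genes (median -0.07, camera adjusted p = 0.014, and adjusted p = 0.38 with an estimated correlation). All 16 cholesterol synthesis genes had negative values and Hmgcs1 fell by 0.23 (median -0.09, camera adjusted p = 0.00031, and adjusted p = 0.38 with an estimated correlation). Adjusted over the list alone, 2 immediate early genes, 1 interferon, 4 hypoxia, 3 clock and 1 cholesterol gene fell. No clock, interferon or cholesterol gene passed with any array but mutant replicate 1 left out, and Npas4 lost its call without wild-type replicate 1 or 2 or mutant replicate 2 or 3. Psat1 rose by 0.39 and Asns fell by 0.34 among 16 genes of the unfolded protein and heat shock response (median 0.02, camera adjusted p = 0.92), and neither passed without wild-type replicate 2 or mutant replicate 2 or 3. No gene passed limma's adjusted p among 29 cytosolic ribosomal proteins, where 8 had an unadjusted p under 0.05, and the list was shifted up (median 0.08, camera adjusted p = 0.0013, and adjusted p = 0.53 with an estimated correlation). None passed among 33 oxidative phosphorylation genes either, where 2 had an unadjusted p under 0.05 (median -0.0068, camera adjusted p = 0.73).

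Several further marker lists were not shifted. No gene passed limma's adjusted p among 20 microglia and macrophage genes (median -0.0049, camera adjusted p = 0.66), of which 5 had an unadjusted p under 0.05. The same held for 18 ependymal and ciliated cell genes (median -0.01, camera adjusted p = 0.72), 17 cartilage and bone genes (median 0.03, camera adjusted p = 0.53), 22 skeletal muscle genes (median 0.04, camera adjusted p = 0.28) and 16 pituitary genes (median -0.01, camera adjusted p = 0.82). Each of those 4 lists had 2 genes with an unadjusted p under 0.05. Without wild-type replicate 1 the cartilage list passed (adjusted p = 0.047). Perp fell among 20 epidermal genes (median 0.02, camera adjusted p = 0.92) and Dct rose by 0.29 among 17 genes of eye and olfactory epithelium (median -0.0047, camera adjusted p = 0.67). The call of Dct was lost without wild-type replicate 2 or mutant replicate 2 or 3. In the list of Xist and Y-linked genes 5 were measured, none passed limma's adjusted p or an unadjusted p under 0.05, and the median was -0.89 (camera adjusted p = 0.58), but 0.01 without mutant replicate 3. Mutant replicate 3 stood apart from the other arrays in these genes, with Xist at 6.27, Eif2s3y at -4.32, Uty at -3.30 and Kdm5d at -2.85. In mutant replicate 2 Xist was at 1.17 while Eif2s3y was at 0.19. The values of mutant replicate 3 are those of a female embryo beside males, which would leave sex unbalanced between the genotypes. The labels give no sex. Without mutant replicate 3 the cycling-cell median was 0.51 with 24 genes risen, and the synaptic median was -0.32.

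Across the 44 lists, camera with the preset correlation called 20, with 7 shifted up and 13 down. In splits of the 6 arrays into 3 and 3 that mix the genotypes, camera called between 5 and 21 lists. Such splits still hold part of the genotype difference, but the count of 20 is not particular to genotype. With an estimated correlation it called 0, and 3 lists had an unadjusted p under 0.05: synaptic and mature neuron genes (0.0055), forebrain transcription factors (0.025) and cycling cells (0.034). Fry, which asks whether a list's genes move one way on balance, called 12, and camera on ranks called 19. Leaving out 1 array moved the median by over 1.5 times in 33 of the 44 lists, 9 of them among the 20 called, and turned its sign in 15 lists, none of them called. The p53 target, hypoxia and Tdp2 neighbour lists were called by fry and not by camera (adjusted p = 0.043, 0.025 and 0.025). Of 838 distinct list genes 153 changed. That count was 93 without wild-type replicate 1, 53 without wild-type replicate 2, 21 without mutant replicate 2 and 85 without mutant replicate 3. Of the 153 genes, 18 passed with any 1 array left out. All 153 kept their sign, which adds no support because they were called on the same arrays. Without mutant replicate 2 the cycling-cell median was 0.52 and the synaptic median -0.38.

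Genomic span was examined because topoisomerases act on long transcribed genes. Of 2298 genes over 100 kb, 379 fell (16.5%) and 42 rose, against 496 falls (2.82%) and 411 rises among 17620 shorter genes. The median log2 fold change was -0.06 for long and 0.02 for shorter genes. As a set, long genes were lower by camera with the preset correlation (p = 1.5e-11), but not past 0.05 with the estimated correlation (p = 0.075). The share that fell increased from 1.55% of genes up to 10 kb to 40.6% of 212 genes over 500 kb, whose median was -0.22. Long neuronal genes such as Opcml (-0.63) and Lrp1b (-0.39) were among them. Spearman's rho of fold change with span was -0.17 across genes, which are not independent replicates. Without mutant replicate 2, 54 long genes (2.35%) and 44 shorter genes (0.25%) fell. Without mutant replicate 1, 482 long genes (21.0%) and 1037 shorter genes (5.89%) fell. Without wild-type replicate 1, wild-type replicate 2 or mutant replicate 3, 188, 90 and 169 long genes fell.

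**Figure D3:**
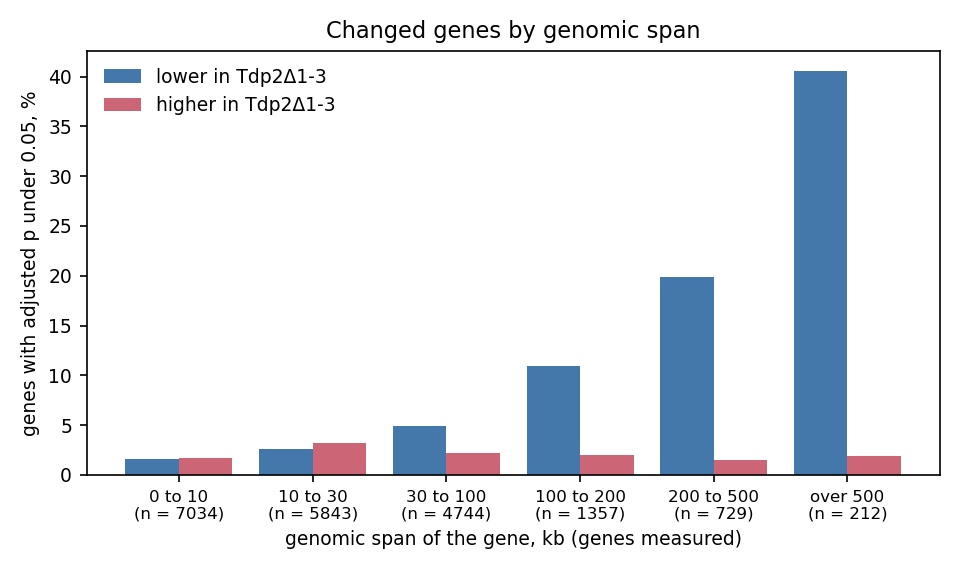
Percent of genes with a limma adjusted p under 0.05, by the gene's genomic span in kb, with lower genes in blue and higher genes in red. The share of lower genes was 1.55% up to 10 kb and 40.6% over 500 kb, while the share of higher genes was 1.71% and 1.89%.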

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

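The tests of the globins and of array scaling were chosen after the results were seen. The other tests were set before the value each one measures was computed, although group results were by then known. A signal also stood in data outside the comparisons: 12 of 5446 array rows that name no gene changed at least 1.5-fold with a limma adjusted p under 0.05, 5 higher and 7 lower in the mutants, and 80 changed at any fold.

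The embryonic globins Hbb-y (3.79) and Hba-x (1.44) rose in all 3 mutant brains. More blood in the mutant brains would raise other red-cell transcripts by a similar amount. The 17 other red-cell rows, adult globins and the embryonic Hbb-bh1 among them, had a median of -0.0097 and a highest value of 0.135. A variant at the beta-globin locus alone would leave Hba-x, on another chromosome, near 0, and its value was 1.442. An axis along which arrays of 1 genotype also differ would spread Hbb-y within a genotype, and its largest range within a genotype was 0.107 of the difference between genotypes. The value of Hba-x argues against a beta-globin variant alone. The small spread of Hbb-y within a genotype is also what gave it a small p, so it is no separate evidence on the shared axis, which stays open. The red-cell values argue against more blood only as far as the other red-cell rows can respond. Levels are centred away, so rows at background or saturated could not be set aside. A difference tied to genotype or to the stage of the embryos may remain, and neither was tested.

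Genes of cycling cells rose (median 0.56) and genes of synapses fell (median -0.39). A plain scaling difference between arrays cannot move lists in opposite ways, and after cyclic loess the synaptic median was -0.298 and the cycling median 0.52. Cyclic loess acted on centred values, so it could not remove a trend with signal level. Such a trend could not be tested, because levels are centred away. Without mutant replicate 3, the array with high Xist, the cycling median was 0.514, which argues against that array as the source. An axis shared with arrays of 1 genotype remains open: across 22580 rows, mutant replicate 2 minus wild-type replicate 2 correlated at 0.471 with mutant replicate 3 minus mutant replicate 1, and at 0.217 with wild-type replicate 3 minus wild-type replicate 1, so a delay of development, litter or dissection may add to or stand for the effect of genotype, which these data cannot separate.

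The median of genes over 100 kb lay below that of shorter genes by a gap of -0.07, and as a set they did not pass camera with an estimated correlation (p = 0.075). Many neuronal genes are long, so the fall of neuronal genes may account for part of it. Within neuronal lists the gap was -0.09 (70 long against 134 shorter genes), and within non-neuronal lists it was -0.0255 (17 against 361). The bound set beforehand, 0.1, exceeded the whole gap and so could not decide, the rule was reset after the values were seen, and 17 long genes are too few to tell. Among genes in neither kind of list the gap was -0.07, but that group holds neuronal genes too. No p is given for these gaps, because genes are not independent.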

How the results depend on the processing

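Tdp2 stayed between -2.18 and -1.96 and kept its call in each limma setting, but not in the plain t-test (adjusted p = 0.082). The robust variance prior and 1 row per gene were tried after the data were seen, and changed no count by over 1.5 times. The count of genes changed 1.5-fold was 7 at 2-fold, 17 with treat against 1.2-fold and 0 with the plain t-test (150 at an unadjusted p under 0.05, 157 by limma), and 60 to 282 with 1 array left out. The count at any fold was 5425 with array weights, 0 with the t-test (4078 unadjusted, 5115 by limma) and 145 to 2501 with 1 array left out. The t-test has fewer degrees of freedom per row, and its smallest adjusted p was 0.082; the cause of the other differences was not tested. With 1 array left out, Tdp2 ranged from -2.18 to -1.96, shifted lists from 18 to 20 and the long-gene median from -0.07 to -0.05. Camera called 0 lists with estimated correlations and fry called 12. Long genes had a median of -0.0573 and p = 0.075 with an estimated correlation. With the replicate block, 2400 genes changed at any fold and 157 at 1.5-fold, red-cell genes lost their list call (adjusted p = 0.10), peripheral neurons gained one (0.042), and 20 lists were shifted. The red-cell call was also lost with all rows (0.075), array weights (0.15) and ranks (0.36), and array weights ended those of the immediate early (0.11) and interferon (0.11) lists. The series text speaks of pairs, but the labels do not say that a number marks a litter. Deviations of same-numbered samples correlated at 0.21, 0.05 and 0.20. Those of differently numbered samples of the 2 genotypes lay between -0.22 and 0.06. Deviations were taken from each genotype's own mean, so positive values for same-numbered samples force lower ones for the rest. Whether numbers mark pairs therefore stays open. The block was left out of the main fit beforehand, because the series text states no paired test. Over named genes, 2467 comparisons of an alternative with the reported value stayed on the same side of the threshold, called or not, 384 lost a call and 124 gained one, and over lists 674, 55 and 18, and no sign turned for a result called in either setting. Signs turned among uncalled results, as for Aldh1a2 (0.12), Pcsk1n (0.18) and Eif2s3y (0.94) with cyclic loess, apoptosis effectors without mutant replicate 1 (-0.01) and peripheral neurons without wild-type replicate 1 (0.0019). A filter on low values, an intensity trend and long genes above the median level were not run, because levels are centred away, and signal over background is likewise unknown.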

Other observations

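The gene families described here were chosen by their symbols after the data were seen. Symbols that share their first letters, up to 4, were grouped into 347 stems of at least 8 genes, and rises and falls were each tested against all other genes (one-sided Fisher's exact test, adjusted over 694 tests), with genes treated as independent. Of the stems 7 passed for rises and 17 for falls. These tests used the calls at any fold from all arrays and were not repeated with an array left out. Of 10 Mcm genes, which encode replicative helicase subunits and partners, 7 rose (adjusted p = 2.3e-07), and of 21 Cenp genes, centromere proteins, 8 rose (adjusted p = 3.6e-06). Of these, Mcm2, Mcm3, Mcm5, Mcm6, Cenpe and Cenpf also stood in the cycling-cell list, and each lost its call without mutant replicate 2. Among 38 genes of the Kif stem, most of them kinesins, 9 rose, including Kif4 and Kif23, and 3 fell, Kif1a, Kif26b and Kif3b (adjusted p = 3.1e-05 for rises).

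Of 13 genes of the Cntn stem, contactins and contactin-associated proteins, 7 fell (adjusted p = 7.3e-05), and of 16 GABA-A receptor subunit genes of the Gabr stem 7 fell, among them Gabra5, Gabrb1 and Gabrg1 (adjusted p = 0.00025). Of 17 synaptotagmin genes 7 fell (adjusted p = 0.00035), of 23 cadherin genes of the Cdh stem 7 fell (adjusted p = 0.0024), and of 364 genes of the Slc stem, most of them solute carriers, 37 fell and 1 rose (adjusted p = 0.00023). There were also 6 falls among 9 genes of the Rasg stem (adjusted p = 7.4e-05), 6 among 12 of the Camk stem (adjusted p = 0.00040), 5 among 8 of the Cpne stem (adjusted p = 0.00056) and 8 among 26 of the Pde stem, 1 of them Pde4dip, which encodes no phosphodiesterase (adjusted p = 0.00065). Some of these genes also stood in the gene lists. Without mutant replicate 2, Syt1, Syt4, Cdh6, Cdh12, Cdh13, Gabrb2 and Cntn4 lost their calls, while Cntn5 and Camk2b kept theirs.

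Genes known to decline or appear as the embryonic brain matures were looked up after the globins had been seen. Igf2bp1, Igf2bp3 and Hmga2, which are highest in early embryos, rose by 0.48, 0.49 and 0.44 (limma adjusted p = 0.0044, 0.010 and 0.0054). Nfix fell by 0.26 (adjusted p = 0.019). Lin28a was at -0.01, Lin28b at -0.04, Bcl11a at -0.07 and Sox6 at 0.24, and none of these 4 passed.

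Single arrays differed in ways the genotypes do not follow, in genes chosen after their values were seen. Hoxa5 was at 1.08, 0.80 and -0.80 in the wild types and at 1.02, -1.05 and -0.95 in the mutants. Wild-type replicate 1 had Gh at 1.57 and Otx2 at -0.89. On the first principal component, 57.9% of the variance, wild types lay at -16.3, -10.9 and -6.81 and mutants at 2.77, 12.5 and 18.7. By order on chromosome 13, 31 genes within 20 positions of Tdp2, a set that differs from the fixed neighbour list, were measured and 6 changed. Without Acot13, 16.7% of them changed, against 6.67% of all genes.

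The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes changed 1.5-fold, 1 split, the real one, gave 150, and the highest of the others gave 1. For genes changed at any fold, 1 split, again the real one, gave 1515, and the highest other gave 1. For gene lists, 2 splits gave 20 or more, and the split of wild-type replicates 1 and 2 and mutant replicate 1 against the rest, which is also how Hoxa5 divided, gave 21. The lowest count of lists among the other splits was 5. For the gap between long and shorter genes, 1 split gave 0.073 or more, and the highest other gave 0.040.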
